A study of Homo sapiens with 6 samples.

How the data were processed

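The study measured total RNA in 12Z cells, an established human endometriosis epithelial cell line, 72 h after transfection with a control siRNA (3 libraries) or with 1 siRNA against LINC01638 (3 libraries). Per the labels' protocols, ribosomal RNA was removed with a depletion kit and libraries were made with a directional kit, so the strand of each RNA is known. Per the submitters' processing notes, STAR 2.7.10b and R 4.2.1 were used with the GRCh38 (hg38) genome. The counts values, as deposited by the authors, were made by mapping reads with STAR and counting them per gene, and they are whole numbers without normalization in 1 table per library. The gene annotation release, trimming and mapping settings are not given in the sources used here. The share of reads listed as mapping to several places is 0 in each table, so genes with near-identical copies are counted only where reads map uniquely.

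Each deposited table lists 62696 genes and 3 columns of counts, without regard to strand, on one strand and on the other. The column for the reverse strand was used, since it fits the directional kit and held 45617234 to 58148664 counts per library, most of the reads. The 4 rows that name no gene stayed out of library sizes and tests. They held unmapped reads (12.3% ± 0.351 of all fragments with control siRNA and 13.0% ± 0.0422 with LINC01638 siRNA), reads outside annotated exons (9.18% ± 0.864 and 13.2% ± 1.67 of mapped reads), reads over several genes (7.49% ± 0.243 and 7.17% ± 0.163 of mapped reads) and reads mapping to several places (0). Gene identifiers were matched to symbols exactly for 61918 genes and without the version suffix for 707 more. Positions, gene classes and 3′ UTRs came from GENCODE 29 on GRCh38, which holds 58251 of the identifiers and may not be the release used for counting. For each gene the longest annotated 3′ UTR was taken, which may not be the one used in these cells.

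Groups and replicate letters were taken from the sample titles and treatment labels. Counts were filtered with edgeR's filterByExpr (minimum count 10, minimum total count 15), which kept 18569 genes, and scaled by the trimmed mean of M-values (TMM). The groups were compared with edgeR's quasi-likelihood F test (robust dispersions, group as the only term), and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Log2 fold changes are LINC01638 siRNA minus control siRNA, and levels are TMM-scaled CPM given as mean ± SD. SE is the absolute log2 fold change divided by the square root of the F statistic. The common biological coefficient of variation was 5.62%. Computations used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6. The tests were run first on simulated data made from the means, dispersions and library sizes of this comparison, with 18185 genes tested. edgeR recovered 49.0%, 59.2%, 73.9% and 93.8% of the 49, 49, 46 and 48 tested genes changed 1.25-fold, 1.5-fold, 2-fold and 4-fold. False calls were 3.65% of all calls for edgeR (5 genes), 6.99% for DESeq2 (10 genes) and 6.38% for limma-voom (9 genes), where the threshold was 5%. These counts from 1 simulated data set are too small to rank the tools. Far fewer genes were changed in it than the 10390 that passed in the real comparison, so its shares may not carry over.

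The genes named in the text follow a rule set before the data were examined. It takes LINC01638, RHOB and HDAC1, the 10 genes with the largest positive and the 10 with the largest negative log2 fold change, and members of the gene lists. The largest changes were taken among protein-coding and long non-coding genes past the threshold with a mean of at least 5 CPM, a symbol that is not a clone name and groups that do not overlap. Of each list the rule takes up to 4 members past the threshold with the lowest p, or up to 2 of the highest mean CPM where none passes. The 38 gene lists were compiled by hand from general knowledge before the data were examined. Beside the genes of the series title they cover EMT, adhesion, matrix and histone deacetylase genes, signalling, cell cycle, stress, interferon, metabolism, RNA classes that report on RNA quality, and markers of stromal, endothelial, immune, ciliated and mesothelial cells. The 35 lists with at least 5 tested members were compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted over lists, and again with the correlation estimated from the data and with fry. Of the lists past the threshold 3, and some members of other lists, are not reported here.

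Alternatives were DESeq2's size factors, DESeq2's Wald test, limma-voom, no filter, a stricter filter (1 CPM in 3 libraries and a mean count of 10), the replicate letter as a block, the column without strand, protein-coding genes only, library sizes without mitochondrial and the 20 most abundant genes, thinning to 45617234 counts per library, an adjusted p of 0.01, a 1.5-fold minimum, and leaving out each library in turn. An offset for GC content, scaling by library totals alone and a wider window around LINC01638 were chosen after seeing the data. Shares between groups of 3 were compared by exact two-sided permutation tests, whose smallest p is 0.1. For the closing observations, each of 16220 words of 7 bases found in at least 50 annotated 3′ UTRs was tested for association with the log2 fold change of 12074 protein-coding genes with a mean of at least 1 CPM. That regression adjusts for 3′ UTR length and GC content. On simulated data with a planted effect it ranked the planted word first in 5 of 5 runs.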

Results

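RNA was measured in 12Z cells, an established epithelial cell line derived from human endometriosis, 72 h after transfection with small interfering RNA (siRNA), short double-stranded RNA that directs the degradation of matching transcripts. The 6 libraries fell into 2 groups of 3: cells given a control siRNA (replicates A, B and C) and cells given 1 siRNA against LINC01638, a long intergenic non-coding RNA (replicates A, B and C). Ribosomal RNA was depleted before strand-specific, paired-end sequencing with 50 bp reads, so that RNAs with and without a poly(A) tail could be counted. The counts assigned to genes came to 55031286, 45617234 and 54775330 in control replicates A, B and C and to 52360090, 50470195 and 58148664 in LINC01638 siRNA replicates A, B and C. The labels name the replicates but do not say that they were separate cultures, so the p-values below measure the spread between these libraries, which may be technical.

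The comparison of the siRNA groups asked, as the title of the series states it, how LINC01638 relates to epithelial-to-mesenchymal transition (EMT), to the gene RHOB and to the histone deacetylase gene HDAC1. LINC01638 (ENSG00000233521.8, GRCh38 chromosome 22, 27221349 to 27224727, minus strand, a gene of 3 exons in its annotated transcripts) was lower in all 3 libraries labelled LINC01638 siRNA. Its counts were 407, 334 and 414 in the control replicates and 125, 103 and 123 in the LINC01638 siRNA replicates, and its level fell from 7.70 ± 0.0943 to 2.11 ± 0.163 CPM (counts scaled to library size; mean ± SD, n = 3 each). This was a loss of 72.6%, a log2 fold change of −1.87 (SE 0.111, edgeR adjusted p = 3.73e-11). RHOB (ENSG00000143878.10, chromosome 2, 20447074 to 20449445, plus strand), which encodes a small GTPase of endosomes and the actin cytoskeleton, fell 3.92-fold, from 509 ± 41.9 to 129.9 ± 2.30 CPM (log2 fold change −1.97, SE 0.0590, edgeR adjusted p = 8.48e-15). HDAC1 (ENSG00000116478.12, chromosome 1, 32292086 to 32333635, plus strand), a histone deacetylase of several corepressor complexes, rose 2.08-fold, from 114 ± 2.80 to 237 ± 4.25 CPM (log2 fold change 1.06, SE 0.0467, edgeR adjusted p = 8.51e-13). All 3 genes also passed the threshold when adjusted over the list alone, and for each gene the 3 libraries of one group lay outside the range of the other. The 3′ untranslated region (UTR) of RHOB, 1389 bases long, holds 1 copy of GAATACA, a 7-base word that LINC01638 also contains and whose presence in 3′ UTRs went with lower fold changes across genes. The 3′ UTRs of NTRK3, INHBB, IQCK, MTDH, SPARC, ITGA11, DLC1, EXO1, CCNA2, DDIT4, KLF6, SDHB and APAF1, lower genes named below, also hold it, as do those of SERPINB9, SPOP, ZMAT3, STS and BCL2L2, which rose. GAATACA is absent from the 3′ UTRs of other lower genes named below, among them MN1, VIM, AXL, FOXC2, SNAI2, JUN and EGR1. Among 12074 protein-coding genes searched, 1439 held it, and so did 705 of the 4707 lower ones. The 3′ UTR of NTRK3, with 3 copies, is 17184 bases long. Holding GAATACA therefore does not by itself set the named genes apart. A single siRNA against LINC01638 without a rescue among these libraries leaves the effects of the siRNA and of its target joined in every value.

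**Figure D1:**
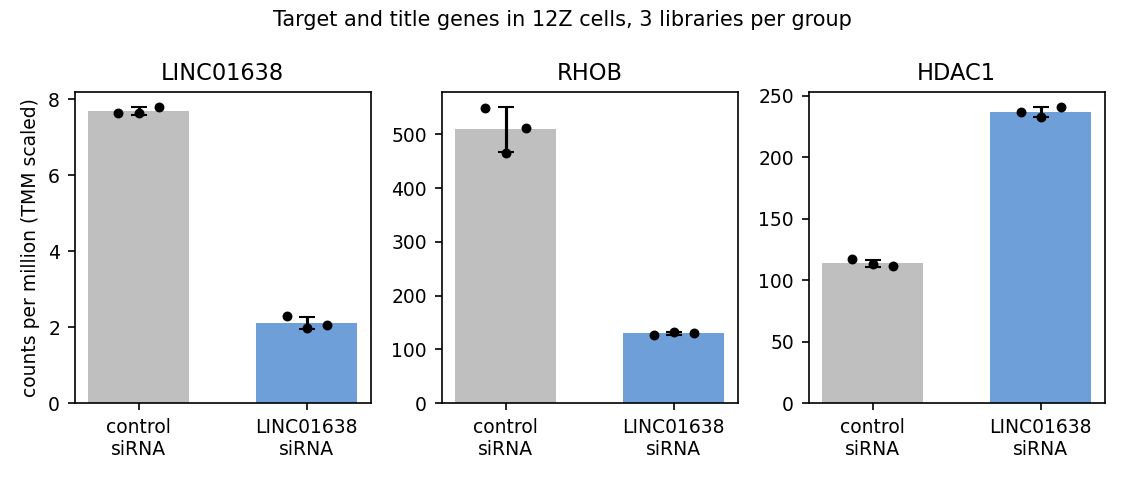
Expression of LINC01638, RHOB and HDAC1 in 12Z cells, in TMM-scaled CPM on the vertical axes. Bars give the mean and error bars the SD of the 3 libraries of each group, and points give the libraries. LINC01638 fell to 2.11 CPM and RHOB to 129.9 CPM, while HDAC1 rose to 237 CPM with LINC01638 siRNA.

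The difference between the siRNAs extended over much of the transcriptome. Of 18569 genes tested, 10390 (56.0%) passed an edgeR adjusted p of 0.05, 4887 higher and 5503 lower with LINC01638 siRNA. Which direction holds more genes depends on the scaling: with library totals alone, chosen after the data were seen, edgeR called 6349 higher and 4288 lower. Most of these changes were small: 4243 genes changed at least 1.5-fold, and 993 rose and 789 fell at least 2-fold. Among protein-coding genes 3884 were higher and 4928 lower of 13586 tested, whereas among long non-coding RNAs 559 were higher and 386 lower of 2715. When the protein-coding genes were scaled and tested by themselves, 4442 were higher and 4519 lower, so their lean towards lower values depends on the scaling too. Of non-coding genes and pseudogenes that lie inside a protein-coding gene on its own strand, where reads of its introns count too, 267 were higher and 32 lower of 950, against 287 and 221 of 1645 outside protein-coding genes, in libraries whose share of reads outside exons was also larger. The first principal component held 91.7% of the variance and separated the groups. Values of the groups did not overlap for 11426 genes (61.5%), where chance gives 10% with 3 libraries against 3.

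Among genes with a mean of at least 5 CPM, the largest rise was that of GDF15, a stress-induced cytokine of the TGF-β superfamily, from 4.91 ± 0.883 to 62.5 ± 9.52 CPM (log2 fold change 3.67, SE 0.153, edgeR adjusted p = 1.17e-07). DHRS2, a short-chain dehydrogenase/reductase, rose 8.08-fold, and the serpins SERPINB2 and SERPINB9 rose 4.98-fold and 3.50-fold. ANKRD1, an ankyrin-repeat protein and YAP target, rose from 33.1 ± 1.98 to 147 ± 5.22 CPM, and the cyclin-dependent kinase inhibitor CDKN1A from 120.5 ± 4.16 to 419 ± 41.1 CPM. The NKG2D ligand gene ULBP2 (log2 fold change 1.76), PLEKHA6 (1.70), LMLN (1.68) and the chloride/proton exchanger gene CLCN4 (1.62) completed the 10 largest rises. ULBP2 has close paralogues, so its count depends on unique mapping and is uncertain to that extent.

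The largest fall was that of the neurotrophin receptor gene NTRK3, from 13.9 ± 0.635 to 1.87 ± 0.712 CPM (log2 fold change −2.91, SE 0.204, edgeR adjusted p = 8.53e-07). MN1, a transcriptional regulator gene on chromosome 22, fell from 34.0 ± 1.29 to 4.63 ± 0.935 CPM (log2 fold change −2.88, edgeR adjusted p = 2.44e-13). The long non-coding RNA LINC00707 fell 5.38-fold, the zinc finger gene ZNF853 5.34-fold and PLPPR3 4.93-fold. INHBB, which encodes the βB subunit of activins and inhibins, fell from 19.4 ± 0.103 to 4.15 ± 0.534 CPM. CAVIN3, a caveola coat gene, fell 4.07-fold, IQCK 4.07-fold and the teneurin gene TENM2 4.07-fold. PTGES, the gene of microsomal prostaglandin E synthase, fell from 37.8 ± 3.57 to 9.51 ± 2.85 CPM (edgeR adjusted p = 4.12e-04).

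**Figure D2:**
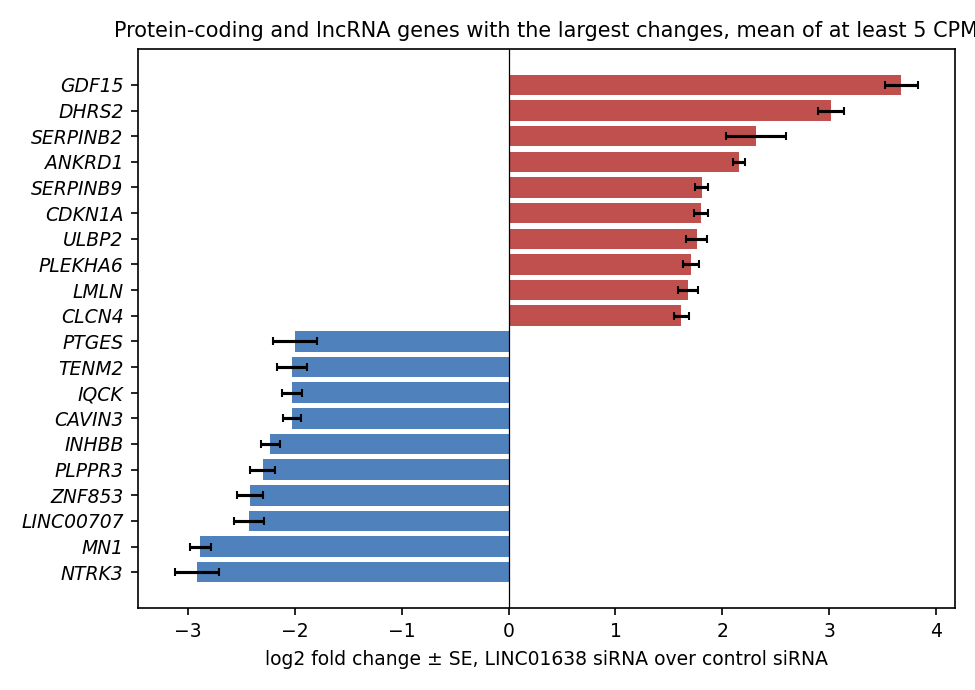
Log2 fold change with LINC01638 siRNA over control siRNA (horizontal axis) for the 10 genes with the largest rise and the 10 with the largest fall under the fixed rule for named genes. Error bars give the SE derived from the edgeR F statistic over 3 libraries per group. GDF15 had the largest rise, 3.67, and NTRK3 the largest fall, −2.91.

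Genes used as markers of mesenchymal cells fell as a group, whereas epithelial markers went both ways. Of 34 mesenchymal markers tested, 27 fell, 2 rose and 5 did not pass, with the same counts adjusted over the list alone (median log2 fold change −0.57; camera adjusted p = 5.58e-08, and adjusted p = 0.494 with an estimated correlation). Vimentin (VIM), the intermediate filament of mesenchymal cells, fell from 2314 ± 71.6 to 979 ± 72.0 CPM, the receptor tyrosine kinase gene AXL from 959 ± 60.9 to 419 ± 23.0 CPM, TAGLN from 68.7 ± 7.19 to 29.1 ± 0.494 CPM and the matrix glycoprotein gene SPARC from 4107 ± 349 to 1883 ± 32.5 CPM. The 2 members that rose, named after their values were seen, were ACTA2 (smooth muscle actin, log2 fold change 0.85) and POSTN (periostin, 0.48). Fibronectin (FN1), also named after its value was seen, stood at 560.4 ± 76.5 CPM in control and 574 ± 93.5 CPM in LINC01638 siRNA libraries and did not pass (edgeR adjusted p = 0.871).

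EMT transcription factor genes fell in 8 of 11 cases and rose in 2, with the same counts adjusted over the list alone (median −0.52; camera adjusted p = 0.00785, and adjusted p = 0.494 with an estimated correlation). FOXC2 fell from 8.75 ± 0.252 to 2.69 ± 0.349 CPM and SNAI2 (Slug) from 12.8 ± 0.742 to 4.17 ± 0.897 CPM, with log2 fold changes of −1.71 and −1.62. TWIST2 (−0.79) and TCF3 (−0.52) fell by less. The 2 that rose, SNAI1 (0.36) and ZEB2 (0.12), were named after their values were seen. Epithelial markers comprised 12 that rose and 14 that fell of 32, with the same counts adjusted over the list alone (camera adjusted p = 0.774). The median of the list was −0.05 and the direction of the camera test down, whereas its mean was 0.09. LSR, a tricellular junction gene, rose from 15.2 ± 0.164 to 37.7 ± 3.03 CPM and the protease inhibitor gene SPINT2 from 3.68 ± 0.0474 to 9.59 ± 1.32 CPM. Keratin 19 (KRT19) fell from 1422 ± 64.7 to 543 ± 72.8 CPM and the hemidesmosome integrin gene ITGB4 from 170.4 ± 21.7 to 63.5 ± 2.90 CPM. E-cadherin (CDH1), named after its value was seen, fell with a log2 fold change of −1.18 (SE 0.107, edgeR adjusted p = 1.38e-08), and stood at 8.14 CPM in control libraries.

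The rise of HDAC1 was not shared by its family as a whole. Histone deacetylase and corepressor genes rose in 9 and fell in 13 of 30 cases, or 10 and 13 adjusted over the list alone (median −0.03; camera adjusted p = 0.764). HDAC9 rose from 6.61 ± 0.439 to 16.3 ± 0.631 CPM, whereas HDAC6, a cytoplasmic tubulin deacetylase, fell 1.62-fold and HDAC4 1.70-fold. In a list of 4 genes fixed from earlier work on LINC01638, MYC fell 1.65-fold (from 138 ± 4.52 to 83.9 ± 1.96 CPM), TWIST1 fell 1.63-fold, MTDH fell 1.28-fold and SPOP rose 1.20-fold. These counts, 1 higher and 3 lower, were the same adjusted over the list alone, and the list was too short for a list test.

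Replication-dependent histone genes, whose mRNAs lack a poly(A) tail and accumulate in S phase, had the lowest median of all lists tested, −0.83. Of 63 tested, 54 fell, 1 rose and 8 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 3.61e-22, and adjusted p = 0.494 with an estimated correlation). H2BC7 fell from 143 ± 6.63 to 47.3 ± 3.22 CPM, H2AC21 from 69.5 ± 3.90 to 21.5 ± 2.29 CPM, H2BC15 from 152 ± 7.48 to 67.3 ± 2.08 CPM and H2BC9 from 124 ± 5.98 to 51.0 ± 3.26 CPM. H2AC7, named after its value was seen, was the member that rose (1.71), at a mean of 0.316 CPM and with 2.03% of its 50-base windows in no other gene's annotated transcripts. That share was 100% for H2BC9, 99.9% for H2BC7, 98.0% for H2AC21 and 89.9% for H2BC15, and at least 90% for 39 of the 59 histone genes that could be searched.

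Mitosis genes fell in 30 and rose in 4 of 50 cases, with the same counts adjusted over the list alone (median −0.21; camera adjusted p = 0.00111, and adjusted p = 0.494 with an estimated correlation). Cyclin A2 (CCNA2) fell 1.88-fold, CDC25B fell 1.74-fold, CDC20 1.58-fold and CENPI 1.57-fold. The 4 that rose, named after their values were seen, were TTK (0.64), CDC25A (0.60), CENPE (0.35) and CENPA (0.25). S-phase genes were mixed, with 23 lower and 11 higher of 51, or 25 and 12 adjusted over the list alone (median −0.11; camera adjusted p = 0.164). Cyclin E1 (CCNE1) rose from 3.52 ± 0.365 to 9.96 ± 0.668 CPM, while GINS1 fell 1.79-fold and EXO1 1.66-fold.

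Apoptosis genes rose in 16 and fell in 8 of 29 cases, with the same counts adjusted over the list alone (median 0.15; camera adjusted p = 0.164). The BH3-only gene BBC3 rose 2.32-fold and the anti-apoptotic gene BCL2L2 2.02-fold, whereas APAF1, the scaffold of the apoptosome, fell 2.56-fold and BOK 1.82-fold.

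Cholesterol and SREBP-regulated lipid genes fell in 23 and rose in 3 of 33 cases, or 25 and 3 adjusted over the list alone (median −0.32; camera adjusted p = 2.34e-06, and adjusted p = 0.559 with an estimated correlation). MVD of the mevalonate pathway fell from 60.6 ± 2.06 to 25.6 ± 1.69 CPM, lanosterol synthase (LSS) 2.03-fold, fatty acid synthase (FASN) 1.79-fold and ELOVL6 1.67-fold. The 3 that rose, named after their values were seen, were MSMO1 (0.29), SC5D (0.21) and IDI1 (0.14). Hypoxia and glycolysis genes fell in 23 and rose in 8 of 39 cases, or 23 and 9 adjusted over the list alone (median −0.20; camera adjusted p = 0.00752, and adjusted p = 0.770 with an estimated correlation). This list lost its camera call with the stricter filter (adjusted p = 0.0563) and with protein-coding genes only (adjusted p = 0.0547). DDIT4 (REDD1) fell from 93.2 ± 4.35 to 28.3 ± 0.690 CPM and adrenomedullin (ADM) from 176 ± 12.4 to 70.2 ± 1.97 CPM, while CA12 fell 1.96-fold and the glycolytic gene PGAM1 fell too (log2 fold change −0.59).

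Immediate early genes and feedback regulators of growth factor signalling fell in 18 and rose in 8 of 29 cases, with the same counts adjusted over the list alone (median −0.29; camera adjusted p = 0.0229, and adjusted p = 0.770 with an estimated correlation). The camera call was also lost with the stricter filter (adjusted p = 0.0923) and with protein-coding genes only (adjusted p = 0.0743). JUN fell from 696 ± 21.5 to 264 ± 5.69 CPM, EGR1 from 729.6 ± 41.6 to 288 ± 22.3 CPM and KLF6 2.45-fold, whereas ETV5, an ETS factor induced by ERK signalling, rose 2.39-fold. Heat shock and NRF2 target genes rose in 14 and fell in 3 of 26 cases, with the same counts adjusted over the list alone (median 0.21; camera adjusted p = 0.00462, and adjusted p = 0.770 with an estimated correlation). The members named by the rule are all NRF2 targets: ferritin light chain (FTL) rose from 1279.7 ± 79.6 to 2878 ± 98.9 CPM, OSGIN1 4.54-fold, the glutathione synthesis gene GCLC 2.05-fold and thioredoxin reductase (TXNRD1) 1.67-fold. The 3 that fell, named after their values were seen, were the heat shock genes DNAJB1 (−0.56), HSPA1A (−0.22) and HSPA8 (−0.17).

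Host genes of small nucleolar RNAs and nuclear long non-coding RNAs rose in 17 and fell in 2 of 23 cases, with the same counts adjusted over the list alone (median 0.48; camera adjusted p = 6.89e-05, and adjusted p = 0.432 with an estimated correlation). MALAT1 rose from 2161 ± 271 to 4309.9 ± 240.0 CPM, SNHG16 from 76.3 ± 4.82 to 194 ± 7.83 CPM, SNHG1 1.55-fold and SNHG3 1.42-fold, while H19 (−1.22) and MEG3 (−0.23), named after their values were seen, fell. In the same libraries the share of mapped reads outside annotated exons was 9.18% ± 0.864 with control siRNA and 13.2% ± 1.67 with LINC01638 siRNA (SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest that 3 against 3 allow). Genes of RNA interference and of sensing double-stranded RNA rose in 11 and fell in 4 of 18 cases, with the same counts adjusted over the list alone (median 0.23; camera adjusted p = 0.0423, and adjusted p = 0.699 with an estimated correlation). Its camera call was lost with the stricter filter, protein-coding genes only, the column without strand and the replicate block (camera adjusted p = 0.0520). It was also lost without control replicate C or LINC01638 siRNA replicate A or B. The sensor genes TLR3 and EIF2AK2 (PKR) rose 2.10-fold and 1.56-fold and TNRC6C rose 1.49-fold, whereas AGO4 fell 2.08-fold. The other members that fell, named after their values were seen, were XPO5 (−0.47), DROSHA (−0.31) and AGO2 (−0.25).

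**Figure D3:**
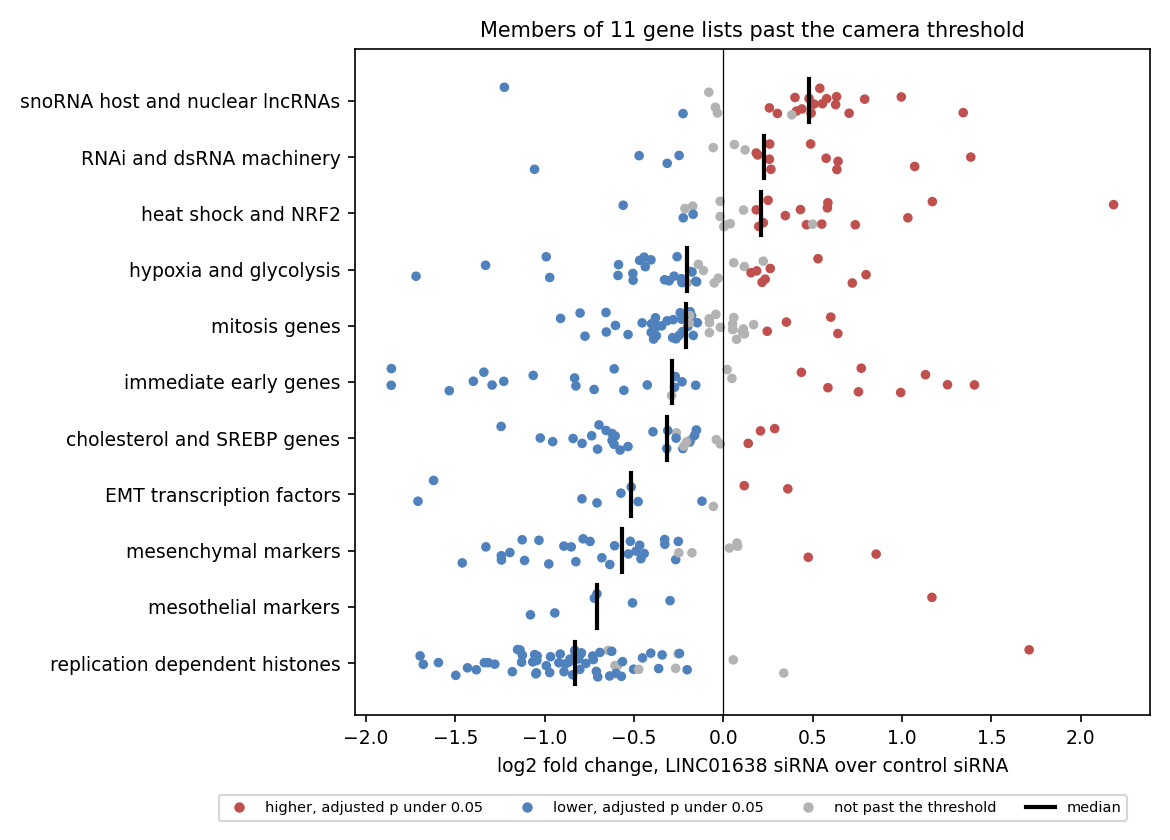
Log2 fold change with LINC01638 siRNA over control siRNA (horizontal axis) of every tested member of 11 of the 14 gene lists past the camera threshold (vertical axis). Points are genes, coloured by direction where they passed edgeR's adjusted p of 0.05 and grey where they did not, and black bars are list medians. The medians run from −0.83 for replication-dependent histones to 0.48 for host genes of small nucleolar RNAs and nuclear long non-coding RNAs.

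Markers of other cell types also moved. Mesothelial markers fell in 6 of 7 cases (median −0.71; camera adjusted p = 0.00752, and adjusted p = 0.432 with an estimated correlation), with WT1 from 172 ± 1.80 to 81.5 ± 3.87 CPM, LRRN4 from 410.1 ± 44.7 to 251 ± 24.0 CPM, CALB2 1.65-fold lower and MSLN 1.42-fold lower. DES (1.17), named after its value was seen, was the member that rose. Stromal and decidual markers fell in 7 and rose in 4 of 13 cases (median −0.25; camera adjusted p = 0.302), with HAND2 1.97-fold and IGFBP3 1.60-fold lower and IGFBP5 2.75-fold higher. Endothelial markers rose in 3 and fell in 2 of 6 cases (median 0.45; camera adjusted p = 0.781), and their direction was up in camera and down in fry. TIE1 fell from 13.4 ± 2.33 to 3.50 ± 1.37 CPM and KDR 1.54-fold, whereas ESAM and CDH5 rose to 1.07 ± 0.164 and 1.78 ± 0.191 CPM. Ciliated-cell markers rose in 1 and fell in 1 of 6 cases (camera adjusted p = 0.915), all at low levels, with PIFO at 0.303 ± 0.0587 CPM and CCDC78 at 1.16 ± 0.169 CPM after LINC01638 siRNA. The median of that list was −0.08 with a camera direction down, and its mean 0.20. CCDC78, at −0.51 here, turned to 0.57 when reads were counted without regard to strand, and lost its call with DESeq2's test, the GC offset, library totals alone and without control replicate B or LINC01638 siRNA replicate B or C. Of 4 immune cell markers, too few for a list test, CD74 rose to 4.62 ± 0.225 CPM and CSF1R to 0.222 ± 0.0176 CPM, and CD14 fell from 48.9 ± 3.54 to 34.6 ± 0.617 CPM. CSF1R, near the floor, lost its call with DESeq2's test (adjusted p = 0.0627) and without control replicate B or C or LINC01638 siRNA replicate B or C. For all 5 lists of this paragraph the counts adjusted over the list alone were the same.

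Several signalling and matrix lists held members moving both ways and did not pass the camera threshold. Matrix and protease genes fell in 18 and rose in 8 of 39 cases, or 20 and 9 adjusted over the list alone (camera adjusted p = 0.127), with MMP15 2.97-fold, TIMP3 2.81-fold, ADAM19 2.32-fold and LOXL1 2.27-fold lower. Integrin genes fell in 6 and rose in 2 of 14 cases (camera adjusted p = 0.202), among them ITGB8 (−1.17), ITGA11 (−0.96), ITGA6 (−0.66) and ITGA3 (−0.44), and the 2 that rose, named after their values were seen, were ITGB3 (0.50) and ITGA1 (0.34). TGF-β and BMP genes fell in 15 and rose in 8 of 27 cases (camera adjusted p = 0.167), with PMEPA1 (−1.15), KLF10 (−0.58), BMP4 (−0.57) and TGFBR1 (−0.56) lower. YAP/TAZ targets rose in 9 and fell in 9 of 24 cases (camera adjusted p = 0.857), with ANKRD1 higher and FOXF2 (−0.90), DLC1 (−0.58) and AXL lower. Wnt genes fell in 7 and rose in 4 of 14 cases (camera adjusted p = 0.652), with DKK3 (−0.82) and NOTUM (−0.80) lower and TCF7L2 (0.74) higher. Notch genes rose in 3 and fell in 2 of 9 cases (camera adjusted p = 0.777), with HEY1 (1.16), JAG1 (0.52) and NRARP (0.51) higher and HES4 (−0.30, not past the threshold with the GC offset) lower, and a median of −0.03 beside a mean of 0.18 and a camera direction up. The counts of integrin, TGF-β and BMP, YAP/TAZ, Wnt and Notch genes were the same adjusted over the list alone.

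Genes of prostaglandin and steroid metabolism and of endometriosis fell in 13 and rose in 10 of 30 cases, with the same counts adjusted over the list alone (median −0.15, camera direction down, mean 0.01; camera adjusted p = 0.777). GREB1, an oestrogen-responsive gene, rose from 0.358 ± 0.129 to 6.15 ± 0.712 CPM, cyclooxygenase 2 (PTGS2) from 1.68 ± 0.318 to 6.83 ± 0.363 CPM and steroid sulphatase (STS) 1.98-fold. Interferon-stimulated genes rose in 21 and fell in 13 of 56 cases, or 22 and 13 adjusted over the list alone (camera adjusted p = 0.162), with TRIM22 (1.14), OAS3 (0.56) and B2M (0.55) higher. Cytokine and NF-κB target genes rose in 11 and fell in 12 of 37 cases, with the same counts adjusted over the list alone (camera adjusted p = 0.777). ICAM1 (0.75) and NFKB1 (0.65) rose, and IL11 (−0.88) and the chemokine gene CXCL12 (−1.07) fell. Genes of the unfolded protein and integrated stress responses rose in 13 and fell in 17 of 42 cases, or 14 and 17 adjusted over the list alone (camera adjusted p = 0.857), with DNAJC3 (0.87) and ATF5 (0.77) higher and the serine synthesis gene PSAT1 2.75-fold lower. The median of that list lay below 0, and its mean above 0, by less than 0.01, with a camera direction up.

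The lists of ribosomal protein, oxidative phosphorylation, mitochondrially encoded and small structured RNA genes did not pass the camera threshold. Cytosolic ribosomal protein genes rose in 16 and fell in 14 of 86 cases, or 15 and 14 adjusted over the list alone (camera adjusted p = 0.777), with RPLP0 1.71-fold higher and RPL7L1 (−0.68) and RPL36AL (−0.48) lower. RPL3L was near the floor in control libraries, at 0.0251 ± 0.0288 CPM, and at 1.44 ± 0.384 CPM with LINC01638 siRNA. Nuclear genes of oxidative phosphorylation fell in 32 and rose in 16 of 79 cases, or 33 and 16 adjusted over the list alone (camera adjusted p = 0.164), with COX6B2 4.25-fold and SDHB 2.25-fold lower and cytochrome c (CYCS) higher (log2 fold change 0.58). Of 13 mitochondrially encoded mRNAs, MT-ND4 fell (−0.41, edgeR adjusted p = 0.0286; not past the threshold with no filter, library totals alone, or without control replicate A or C or LINC01638 siRNA replicate B), and 0 passed edgeR's test adjusted over the list alone, with 2 at an unadjusted p under 0.05 (camera adjusted p = 0.536). Small structured RNAs rose in 2 and fell in 1 of 11 cases, with the same counts adjusted over the list alone (camera adjusted p = 0.906), namely RNU5B-1 (0.52), SCARNA7 (0.44) and RN7SL1 (−0.29, not past the threshold with the GC offset). Their median was −0.09 and their mean 0.07, with a direction up in camera and down in fry.

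Around LINC01638, MIATNB was the only gene within 500 kb with enough counts to be tested. It lies on chromosome 22 from 26672767 to 26780207 on the plus strand, and stood at 2.24 ± 0.144 CPM in control and 2.99 ± 0.137 CPM in LINC01638 siRNA libraries (log2 fold change 0.41, SE 0.135, edgeR adjusted p = 0.0144). MIATNB lost its call without LINC01638 siRNA replicate A. MN1, 1 of the 10 genes with the largest falls, lies 524 kb from LINC01638 on the same strand (27748277 to 27801498), just outside that window. In a wider window of 1000 kb, chosen after the data were seen, 8 genes passed the edgeR threshold. MIATNB, PITPNB and TFIP11 were higher, and MN1, TPST2, TTC28, ASPHD2 and HPS4 were lower. The other tested genes of these classes there, MIAT, TTC28-AS1, TFIP11-DT and SRRD, did not pass. Since 56.0% of all genes tested passed, this count by itself shows no local effect.

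Of the 35 lists long enough to test, 14 passed the camera threshold with a preset correlation between genes, 4 higher and 10 lower, and 0 passed with the correlation estimated from the libraries, where 3 had an unadjusted p under 0.05. The fry test, which asks whether the genes of a list move on balance in one direction and compares them with no other genes, called 20 lists, and 34 when changes in either direction counted.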

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

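The first result below comes from reads that the gene comparison does not use, the second from the count column of the opposite strand. Both were higher than in the control libraries. The tests of their explanations were fixed before their results were seen, except the comparison with a rise of 4.96 CPM on the annotated strand, which was chosen afterwards. The share of mapped reads outside annotated exons was 15.1%, 12.3% and 12.1% in LINC01638 siRNA replicates A, B and C (mean 13.2% ± 1.67), against 8.32%, 9.18% and 10.1% in control replicates A, B and C (mean 9.18% ± 0.864; exact two-sided permutation p = 0.1, the smallest that 3 against 3 allow). The opposite-strand column held 6.66% ± 0.0362 of the counts of both strand columns with LINC01638 siRNA and 6.47% ± 0.0200 with control siRNA (n = 3 each, exact two-sided permutation p = 0.1). Without regard to strand, 12.5% of mapped reads lay outside exons with LINC01638 siRNA and 8.57% with control siRNA, little below the shares above. Few reads therefore lay over a gene on the opposite strand alone. Most reads of that column lay where genes of both strands overlap, and can be counted in the comparison too.

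For the larger share of reads outside exons, genomic DNA in the libraries and more unspliced RNA were weighed. DNA gives reads of both strands alike, but over the exons of 381 olfactory receptor genes the counts on the annotated strand, scaled to CPM of all fragments, changed by −0.124 (from 4.08 ± 0.115 to 3.96 ± 0.146, n = 3 each), where an even spread of the extra reads over the genome needs a rise of 4.96, and those on the opposite strand rose from 0.767 ± 0.0540 to 1.48 ± 0.126. No rise on the opposite strand, the bound written beforehand against DNA, was not met, but DNA would raise both strands alike, so these values argue against it as the whole source. Non-coding genes and pseudogenes that lie inside a protein-coding gene on its own strand, and so count its intron reads, had a median log2 fold change of 0.47 (950 genes). The median was 0.05 for 1462 inside on the opposite strand and 0.08 for 1645 outside protein-coding genes. The difference from those outside was 0.39 (95% bootstrap interval 0.33 to 0.44, resampling genes and not libraries). This is consistent with more unspliced RNA in the LINC01638 siRNA libraries, and whether it arose in the cells, as a response to the siRNA or to loss of LINC01638, or during RNA preparation stays open and untested.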

How the results depend on the processing

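LINC01638, RHOB and HDAC1 kept their direction and stayed past the threshold under each alternative that tests them (LINC01638 is not tested among protein-coding genes only). Counts of genes past the threshold, higher and lower stayed within 1.5 times of 10390, 4887 and 5503, between 8394 (adjusted p under 0.01) and 10637 (library totals alone) for all genes, except that 4243 changed at least 1.5-fold, a cause that lies in the added fold minimum. Values of named genes were compared under the alternatives other than the adjusted p of 0.01 and the 1.5-fold minimum. Of these, 2734 kept direction and call and 18 kept direction only (CSF1R, CCDC78, MT-ND4, HES4 and RN7SL1). CCDC78 made up the 1 that reversed, with a log2 fold change of 0.57 in the column without strand, and the cause was not tested. Under the 1.5-fold minimum further named genes lose their call, such as SPOP (1.20-fold) and MTDH (1.28-fold). Of list values, 207 kept direction and call and 16 kept direction only (hypoxia, immediate early and RNA interference genes among them). The number of lists past the camera threshold went from 14 to 19 with no filter, 9 with the stricter filter and 8 with protein-coding genes only, where fewer genes were tested, and to 0 with an estimated correlation. Neighbours of LINC01638 past the threshold numbered 1 within 500 kb, 2 with no filter, 0 among protein-coding genes, 8 within 1000 kb and 0 to 2 when leaving out 1 library: 0 without LINC01638 siRNA replicate A, and 2 without control replicate A, control replicate C or LINC01638 siRNA replicate B; the cause was not tested. Scaling by library totals alone moved every log2 fold change by 0.10, and DESeq2's size factors by 0.01, so medians are relative to the TMM scale. No sign was seen that the replicate letters pair the samples. Correlations of deviations between groups over 9645 genes were −0.34 for A, −0.21 for B and 0.01 for C, and control B correlated best with LINC01638 siRNA A (0.33). As deviations from means of 3 libraries, these values cannot exclude shared cultures or days. With the replicate block 9962 genes passed, 9885 of them shared with the unblocked fit, and the RNA interference list had a camera adjusted p of 0.0520. Chosen after seeing the data were library totals alone, the window of 1000 kb and the GC offset, which gave 10169 genes.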

Other observations

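A further 3 gene groups were picked after their values were seen, so their list tests are not independent evidence. All 6 tested genes of NKG2D ligands, surface proteins that mark stressed cells for natural killer cells, rose with LINC01638 siRNA (median log2 fold change 1.49; camera adjusted p = 3.48e-05, and adjusted p = 0.0690 with an estimated correlation). MICB rose from 42.8 ± 1.76 to 124 ± 9.24 CPM, ULBP3 from 7.89 ± 1.06 to 21.2 ± 1.18 CPM and ULBP1 from 0.477 ± 0.142 to 2.20 ± 0.217 CPM, with RAET1G (1.40), ULBP2 (1.76) and MICA (0.24) also higher. Subunit genes of the vacuolar ATPase, the proton pump of lysosomes, rose in 13 and fell in 1 of 19 cases (median 0.49; camera adjusted p = 2.52e-05, and adjusted p = 0.0690 with an estimated correlation). ATP6V1D rose from 29.1 ± 1.87 to 86.2 ± 0.649 CPM and ATP6V1H from 55.4 ± 0.947 to 87.3 ± 2.83 CPM, while ATP6V1G2, at 0.555 CPM in control libraries, fell (−1.32). Tubulin genes fell in 8 of 11 cases and rose in 0 (median −0.71; camera adjusted p = 2.52e-05, and adjusted p = 0.0690 with an estimated correlation). TUBA1A fell from 231 ± 9.67 to 58.7 ± 2.31 CPM, TUBB6 from 487 ± 20.3 to 235 ± 8.46 CPM and TUBB2A from 98.3 ± 4.79 to 46.4 ± 0.793 CPM, and TUBB3 (−0.28), TUBA4A (0.11) and TUBA8 (0.49) did not pass. Tubulin genes are close paralogues, and their single values depend on unique mapping.

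Of the tests below, those of RHOB, of a shorter seed match, of scaling by library totals and of histone genes without copies were chosen after the result was seen. For S-phase genes, the spread of members was weighed in place of the interval of the median, the rule written beforehand. In the whole comparison, 1 of the 10 splits of the 6 libraries into 3 and 3 gave as many genes, the real one with 10390, and the highest of the others gave 0 in edgeR. With 10 splits no share under 0.05 is possible.

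The genes lower with LINC01638 siRNA were weighed against off-targets of the siRNA seed, the short stretch by which an siRNA can bind 3′ UTRs, and against scaling. Of all 7-base words, GAATACA had the lowest standardized association with the log2 fold change, −15.3 over 1439 genes. AATACAA, the lowest word absent from LINC01638, which shares 6 of the bases of GAATACA, had −10.2. GAATACA lies in exon 2 of both annotated LINC01638 transcripts (GRCh38 chromosome 22, 27224291 to 27224297). LINC01638 holds 5.59% of all words tested, and the sequence of the siRNA is not given in the sources used here. The median log2 fold change was −0.25 where GAATACA was followed by A (428 genes) and −0.12 where it was not (1011 genes). It was −0.04 with neither the word nor its last 6 bases followed by A (8670 genes). Of 4707 lower genes 705 held GAATACA, where 445 were expected from length and GC content. The word was picked for its low association in these same fold changes, so these medians and counts largely restate that choice. Among genes without GAATACA the shorter match, AATACAA, had an effect of −0.10 (95% interval −0.12 to −0.07) at equal length and GC content. The unadjusted median of its 1965 genes was −0.04 too. As AATACAA was already known to be low, this shows only that its association does not rest on genes with GAATACA alone. A lowest word that lies in LINC01638 fits seed off-targets for a part of the lower genes, while 4002 lack the word. As for scaling, 4288 genes were lower with library totals alone, so the choice of TMM over library totals is not the whole cause. That setting moves every log2 fold change by 0.10, where changed genes had a median absolute value of 0.49, so most lower genes had to stay lower. Both scales are relative, so a change in the total RNA of the cells was not tested. For RHOB (log2 fold change −1.97), which holds 1 copy not followed by A, a seed effect and an effect of LINC01638 loss cannot be told apart with 1 siRNA, although 7 of the 1439 genes with the word, RHOB included, fell as far, and loss of LINC01638 stays open, untested, for all lower genes.

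For the lower replication-dependent histone mRNAs (median −0.83, 95% bootstrap interval −0.92 to −0.71), a lower yield of RNAs without a poly(A) tail would take the small structured RNAs along. Their median of −0.0921 (−0.21 to 0.44), with the lowest member at −0.39, argues against that. These intervals resample genes, not libraries, and do not measure the spread between libraries. The correlation between genes estimated from the libraries was 0.56 for histones and 0.40 for small structured RNAs. Reads shared between near-identical copies are argued against by the genes without such a copy (at least 90% of their 50-base windows in no other gene's annotated transcripts), of which 38 of 39 fell (median −0.86; 59 of the 63 genes could be searched). Fewer cells in S phase would, by the rule set beforehand, bring the median of the S-phase genes below −0.41. Their median was −0.11 (95% bootstrap interval −0.17 to −0.0020), which by that rule argues against it. But the S-phase genes went both ways (SD of members 0.388), so their median may not report on the share of cells in S phase. Mitosis genes (30 lower, 4 higher) and CCNA2 (−0.91) fell while CDKN1A rose (1.80). Fewer cells in S phase and a change of histone mRNA itself therefore cannot be told apart here. A response of histone mRNA itself to the siRNA or to loss of LINC01638 stays open as an untested hypothesis.

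In the other direction, AGCAACC, absent from LINC01638, was the 7-base word with the highest association with the log2 fold change, 7.42 over 943 genes, against 4.71 for the highest word that shares no 5 bases with it. The 3′ UTRs of LMLN (11 copies), SERPINB9, EIF2AK2, OAS3, GCLC, RPLP0 and IGFBP5, higher genes named above, hold AGCAACC. Those of NTRK3, INHBB and KLF6, which fell, hold it too. The sequence of the control siRNA is not given in the sources used here.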
